A study of Mus musculus with 2 samples.

How the data were processed

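The data were single-nucleus RNA sequencing of quadriceps muscle from WT mice and from mice without Cavin1 (older symbol Ptrf), 1 library of each genotype. Per the labels' protocols, muscle was minced and homogenised in detergent buffer, and nuclei were filtered and spun before droplet capture on the 10x Genomics platform. The deposited values are raw UMI counts per gene and barcode, made with Cell Ranger 6.0.0 per the file headers. The submitters' processing notes also name STAR, Seurat 4.1.1 and the genome builds mm10 and GRCm38. The role of Seurat, the annotation release, whether introns were counted, whether strand was used and how barcodes were called as nuclei are not given in the sources used here. Nuclear RNA is rich in introns, so long genes and genes with internal priming sites can gain UMIs that a count of mature transcripts would not hold.

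The 53700 features carry Ensembl gene IDs and symbols. Of these, 52093 matched the GENCODE M21 annotation of GRCm38 by ID and 49975 also by symbol. The remainder, among them the ID of Rn18s, are absent from that release, so coordinates and lengths are given only for matched IDs. Of the 45 different genes named by rank, 20 overlap another annotated gene on their own strand and 14 more on the opposite strand only, so that part of their UMIs is of uncertain origin. For 81 symbols shared by several IDs, the most abundant ID was used.

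Nuclei with at least 200 genes and at most 5% mitochondrially encoded UMIs were kept, 10272 of 10280 barcodes in WT and 7762 of 7766 in the knockout. The lowest total was 408 UMIs in WT and 500 in the knockout. Scrublet scores were computed per library with an expected doublet rate of 6%, as part of scanpy. The caller marked 0 doublets in either library and so did not work here; doublets therefore stayed in, and 221 knockout nuclei carried both Xist and Y-linked UMIs. Both libraries were log-normalised and clustered together without integration, on 2000 variable genes, 30 principal components and 15 neighbours, by the Leiden method at resolution 1 with seed 7.

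Each of the 22 clusters was scored for 20 marker lists, which left out only the general myonuclear list. The score was the mean log2 ratio of marker levels to those of the other clusters. A class name followed by "-like" was given at a score of at least 2 with at least 3 markers detected. Clusters with at least 2 of a set of long neuronal or repeat-rich transcripts among their 10 leading genes were left unnamed, and the others were called myonuclei where pan-myonuclear transcripts reached 0.5 times their median over clusters. These thresholds were set after the data were seen. They left 13.9% of WT and 0.258% of knockout nuclei in the repeat-led cluster, and 0% and 0.348% in another unnamed cluster. Nuclei of the neuromuscular and myotendinous junctions were counted within the myonuclei. No cluster of a compared class had more markers of another class than of its own among its leading genes. Cluster 7, with 243 of the 253 WT adipocyte-like nuclei, had 0 adipocyte markers among them. Its score was 2.25, near the cut of 2, and its pan-myonuclear transcripts were at 43303 CPM. Cluster 18, with most knockout adipocyte-like nuclei, had a score of 4.58 and 7558 CPM.

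UMIs were summed per library and class. Ratios were taken of CPM of the class total, with 0.5 UMI added to each sum, and carry exact conditional binomial intervals; sums carry exact Poisson intervals and shares exact Clopper-Pearson intervals, all at 95%. Where 1 library had 0 UMIs, a fold was computed with it set to a floor of 3 UMIs. This fold is no exact bound, since the other sum is taken as free of error. Nuclei are not replicates, so no test between genotypes was made, and genes were named by size alone. For each gene list, the median log2 ratio over members with at least 20 UMIs was set against 10000 random lists of the same size matched on mean CPM in 20 bins. This percentile describes these libraries only, and the random lists were not matched on gene length, with which the ratios also varied. Medians of fewer than 3 members were not computed. Classes were compared where both libraries held at least 100 nuclei, which left myonuclei-like, fibro-adipogenic-like, macrophage-like and adipocyte-like nuclei. Myosin heavy chain calls per nucleus were made after thinning each nucleus to 500 UMIs, for which 2055 WT and 0 knockout nuclei were too shallow.

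The named-gene rule, marker lists, gene lists, filters and most alternatives were fixed before the data were examined. In myonuclei-like nuclei the rule takes, among genes with at least 100 UMIs whose interval lies beyond 2-fold, the 12 highest and 12 lowest by the interval bound nearest to no difference. Predicted gene models, mitochondrially encoded, ribosomal protein, haemoglobin and sex-linked marker genes and Cavin1 were left out of the ranking, as were genes whose level was below 0.25 times that of any other large class of the same library. In each other class it takes the 4 highest and 4 lowest genes with at least 30 UMIs whose level exceeds that of myonuclei-like nuclei of the same library. From each list it takes the 2 highest and 2 lowest members; any other gene is said to have been chosen after its values were seen. A few genes taken by these rules are not reported here by name, but stay in the counts and medians of their lists.

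The fixed alternatives were at least 500 genes per nucleus, at most 1% mitochondrially encoded UMIs, doublets kept, resolution 0.5, each library clustered on its own, nuclei with at least 1000 UMIs, thinning to 500 UMIs, median-of-ratios scaling, totals without mitochondrially encoded and the 20 most abundant genes, Myh4-led myonuclei only, list members with at least 100 UMIs and 5 UMIs added. Added after the data were seen were removal of the top 6% of doublet scores, counting the repeat-led cluster as myonuclei, the split by Xist and Y-linked UMIs, and subtraction of the myonuclear profile of the same library in proportion to Ttn.

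The ratio, list and subtraction steps were tested on simulated WT and knockout sums, drawn with counting error alone from the profile of all WT barcodes. In all, 200 genes were altered, and the 10084 genes with at least 100 UMIs were assessed. The intervals covered the true ratio for 95.9% of genes. Of 89 genes altered 4-fold, 88 had an interval beyond 2-fold, as did 3 of 90 altered 2-fold and 0 of 9905 unaltered ones. A list shifted by 0.5 log2 units reached percentile 100 against 21.2 unshifted. An admixture of 40% was estimated as 40.0%, in a simulated class without Ttn of its own, as the subtraction assumes. These simulations check the calculations only. They held no difference between libraries like those of Rn18s or of long genes, so they say nothing of such differences. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9.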

Results

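Single-nucleus RNA sequencing was carried out on the quadriceps, the large extensor muscle of the thigh, of C57BL/6N mice aged 3 months that were wild type (WT) or lacked Ptrf. Ptrf is the older symbol of Cavin1, which encodes a coat protein required for caveolae, the flask-shaped pits of the plasma membrane, and whose loss in people causes lipodystrophy with muscular dystrophy. The design asks how the nuclei of a muscle without this protein differ from those of a normal one. There was 1 library per genotype, so no difference below has a replicate check and every value describes these 2 libraries. The number and sex of the mice behind each library are not given in the sources used here.

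The WT matrix held 10280 barcodes and 9746980 unique molecular identifiers (UMIs), and the knockout matrix held 7766 barcodes and 16052317 UMIs. Filtering kept 10272 WT and 7762 knockout nuclei, with medians of 703 and 1562 UMIs and of 413 and 831 detected genes. Transcripts of Ttn, the giant sarcomeric spring protein, made up 6.82% of WT and 4.12% of knockout UMIs. Rn18s, ribosomal RNA that poly(A) capture should largely exclude, made up 8.07% of WT and 2.90% of knockout UMIs, whereas the nuclear noncoding RNA Malat1 made up 6.67% and 6.47%. All intervals are exact 95% intervals and cover counting error only. Levels are given as CPM, the UMIs of a gene scaled by the total of its class, and log2 ratios are knockout over WT after adding 0.5 UMI to each sum.

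Cavin1 was all but absent from the knockout library. Over all nuclei it had 75 UMIs in WT, or 7.70 CPM (6.06 to 9.65), and 2 UMIs in the knockout, or 0.125 CPM (0.0151 to 0.450), a level 61.8-fold lower (16.5 to 519). Myonuclei-like nuclei held 35 WT UMIs and 0 knockout UMIs, 18.6-fold lower with the knockout set to a floor of 3 UMIs. The exact interval of the knockout to WT ratio had 0.0698 as its upper end. In WT the level was far higher in adipocyte-like nuclei, at 79.6 CPM (48.6 to 123) from 20 UMIs, and these nuclei also held both knockout UMIs, at 1.00 CPM (0.121 to 3.62). Fibro-adipogenic-like nuclei had 5 WT UMIs and 0 in the knockout, with 0.574 as the upper end of the knockout to WT ratio. Macrophage-like nuclei had 3 and 0 UMIs, which is too few to compare. The gene (ENSMUSG00000004044) lies on the minus strand of chromosome 11, from 100956733 to 100970887 in GRCm38, and no other annotated gene overlaps it. Which part of it was deleted is not given in the sources used here.

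Joint clustering gave 22 clusters, which were named from fixed marker genes. Adipocyte-like nuclei stood out: they made up 2.46% of WT nuclei (2.17 to 2.78; 253 nuclei) and 13.7% of knockout nuclei (12.9 to 14.5; 1062 nuclei). The WT share rests mostly on cluster 7 (243 WT and 87 knockout nuclei), whose marker score of 2.25 was near the cut of 2. Cluster 18, with a score of 4.58, held 10 WT and 975 knockout nuclei. Fibro-adipogenic-like nuclei, the interstitial fibroblast lineage that can form both scar and fat, made up 4.23% (3.84 to 4.63) and 7.49% (6.91 to 8.09). Lymphatic endothelial-like nuclei made up 0.253% (0.165 to 0.371) and 2.38% (2.06 to 2.75), and blood endothelial-like nuclei 0.107% (0.0535 to 0.192) and 1.11% (0.887 to 1.37). Lymphocyte-like nuclei numbered 2 in WT and 75 in the knockout. Satellite-like nuclei, the Pax7-expressing muscle stem cells, went the other way, at 0.681% (0.532 to 0.860) in WT and 0.129% (0.0618 to 0.237) in the knockout. These were 70 and 10 nuclei; with at most 1% mitochondrially encoded UMIs they were 99 and 51, and at resolution 0.5 or with at least 500 genes no satellite-like or blood endothelial-like cluster was found.

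Macrophage-like nuclei made up 1.43% (1.21 to 1.68) of WT and 2.45% (2.12 to 2.82) of knockout nuclei. Mural-like nuclei, which carried pericyte and smooth muscle markers, were at 1.12% and 1.13%. Myonuclei-like nuclei made up 75.8% (75.0 to 76.7) of WT and 70.1% (69.0 to 71.1) of knockout nuclei. The class includes the nuclei under the neuromuscular junction, at 0.409% and 0.425%, and those at the myotendinous junction, at 1.13% and 1.17%. A cluster led by the repeat-rich transcripts Gm10801 and Gm10800 and by neuronal genes such as Chl1 and Csmd3 was left unnamed. It held 13.9% of WT nuclei (1425) and 0.258% of knockout nuclei (20). Its pan-myonuclear transcripts were at 102385 CPM, against 93657 and 105532 CPM in the myonuclei-like clusters 0 and 1. Only the rule on leading genes kept it from being named myonuclei. The myonuclei-like difference of −5.77 percentage points turned to 32.6 at a clustering resolution of 0.5, where unnamed clusters of this kind held 5547 WT nuclei, to 29.6 in nuclei with at least 500 genes and to 7.38 in nuclei with Y-linked transcripts alone, but was −19.4 with the unnamed cluster counted as myonuclei. The fibro-adipogenic-like difference of 3.26 points turned to −2.04 when each library was clustered on its own and was 0.377 in nuclei with at least 1000 UMIs, where the macrophage-like difference of 1.02 points was 0.419.

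Marker UMIs summed over all nuclei, which need no clusters, gave some of the same contrasts. The marker lists were those that named the clusters, so these sums are not separate evidence. The adipocyte markers were 5.61-fold higher in the knockout library (5.32 to 5.92), the lymphatic endothelial markers 2.02-fold (1.82 to 2.25) and the fibro-adipogenic markers 1.79-fold (1.70 to 1.89). Endothelial markers were 1.27-fold higher (1.19 to 1.35). The nuclear shares rose far more than these markers, from 0.107% to 1.11% for blood endothelial-like and from 0.253% to 2.38% for lymphatic endothelial-like nuclei. With each library clustered on its own, 0 WT nuclei fell in either endothelial-like class, so the size of these rises depends on the clustering. Satellite cell markers had a knockout to WT ratio of 0.393 (0.329 to 0.466), smooth muscle markers 0.289 (0.244 to 0.341) and T or NK cell markers 0.432 (0.369 to 0.506). Macrophage markers, at 0.790 (0.722 to 0.866), T or NK cell markers and B cell markers, at 0.822 (0.705 to 0.960), went against the nuclear shares of macrophage-like and lymphocyte-like nuclei.

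**Figure D1:**
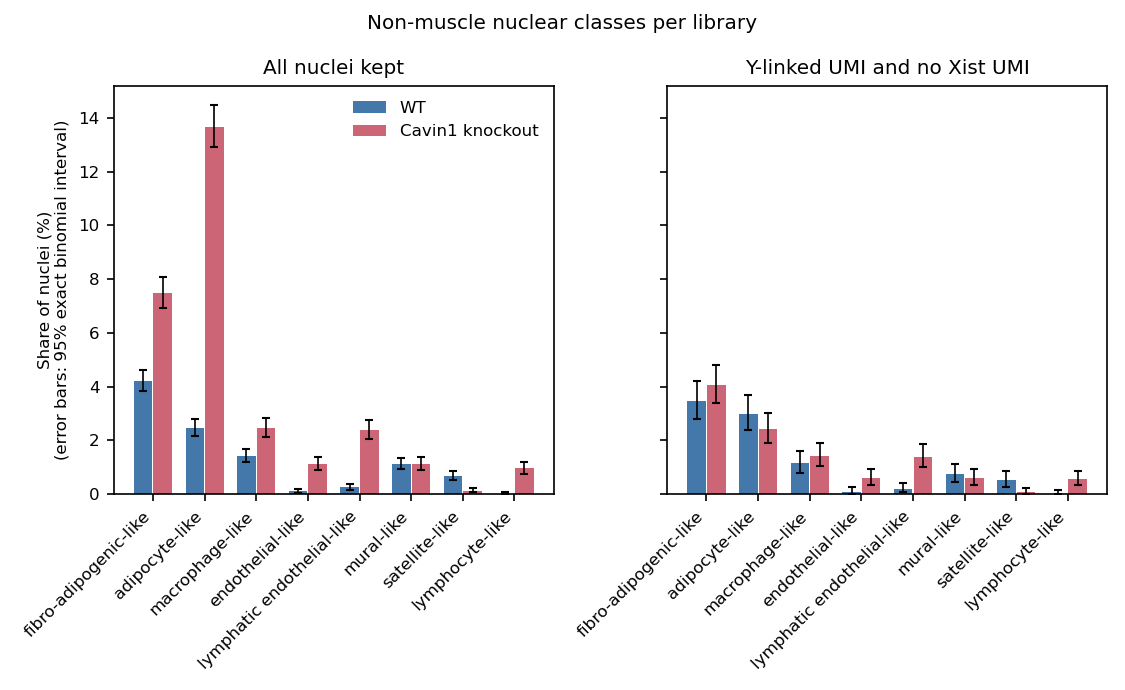
Share of nuclei in percent (y axis) for 8 non-muscle nuclear classes (x axis) in the WT and Cavin1 knockout libraries, over all nuclei kept (left) and over nuclei with a Y-linked UMI and no Xist UMI (right). Error bars are exact 95% binomial intervals; the adipocyte-like share was 2.46% in WT and 13.7% in the knockout on the left, and 2.98% and 2.42% on the right.

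Sex-specific transcripts split the knockout library. Xist, the noncoding RNA made from the inactive X chromosome, had 4 UMIs in the WT library and 4358 in the knockout, while the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together had 3962 and 7096. Of the knockout nuclei, 1527 carried Xist and no Y-linked UMI, 3103 carried a Y-linked UMI and no Xist, 221 carried both and 2911 neither; in WT only 2 nuclei carried Xist alone, against 2721 with Y-linked UMIs alone. Among knockout nuclei with 1 of the 2 signals, Xist alone marked 17.3% (16.0 to 18.6) of myonuclei-like, 45.9% (39.4 to 52.6) of fibro-adipogenic-like, 49.4% (38.5 to 60.4) of macrophage-like and 90.3% (88.0 to 92.3) of adipocyte-like nuclei. Between Y-marked nuclei the adipocyte-like share was 2.98% (2.37 to 3.69; 81 nuclei) in WT and 2.42% (1.91 to 3.02; 75 nuclei) in the knockout. Among Xist-marked knockout nuclei it was 45.8% (700 nuclei). Between Y-marked nuclei the fibro-adipogenic-like shares were 3.45% and 4.06%, with overlapping intervals, as were the macrophage-like shares, 1.14% and 1.42%, whereas lymphatic endothelial-like nuclei were still at 0.184% (0.0597 to 0.428) and 1.39% (1.00 to 1.86). Nnt, which carries an inactivating deletion in C57BL/6J and not in C57BL/6N mice, had 47 WT and 98 knockout UMIs. Comparisons within a class were therefore also made between Y-marked nuclei where enough UMIs were left, an alternative chosen after the data were seen. In the knockout, both signals were held by 80 myonuclei-like, 22 fibro-adipogenic-like, 4 macrophage-like and 94 adipocyte-like nuclei. Y-marked knockout nuclei may thus include Xist-expressing ones with stray Y-linked UMIs, so these comparisons are not strictly within 1 sex.

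The fastest isoform made up more of the myosin heavy chain transcripts in the knockout, although its own level was lower. Of the summed UMIs of the 4 adult isoforms in myonuclei-like nuclei, 31155 in WT and 35823 in the knockout, Myh4 (type IIb) made up 69.1% (68.5 to 69.6) and 80.7% (80.3 to 81.1). Myh1 (IIx) made up 18.4% (18.0 to 18.9) and 12.2% (11.9 to 12.6), and Myh2 (IIa) 12.2% (11.9 to 12.6) and 6.22% (5.97 to 6.47). Myh7, the slow type I isoform, was rare in both, at 0.266% (0.212 to 0.330) and 0.846% (0.754 to 0.946). As levels, Myh4 was at 2767 and 2336 CPM (log2 ratio −0.24, −0.27 to −0.22), and Myh1 (−1.06) and Myh2 (−1.45) were lower by more. Assigning each nucleus thinned to 500 UMIs to its leading isoform gave Myh4 75.3% (74.1 to 76.5) of 4992 WT and 82.9% (81.7 to 84.1) of 3916 knockout nuclei. The developmental isoforms Myh3, with 7 and 3 UMIs, and Myh8, with 11 and 9, were near the detection limit. The Myh4 difference of 11.7 percentage points was 36.3 in nuclei with at least 500 genes, 27.1 at resolution 0.5, 8.82 in thinned nuclei and 18.1 between Y-marked nuclei, but −2.88 for Xist-marked knockout nuclei set against Y-marked WT nuclei. The Myh7 difference of 0.579 points was −0.028 in nuclei with at most 1% mitochondrially encoded UMIs and 0.074 between Y-marked nuclei.

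Within myonuclei-like nuclei, the 12 genes ranked highest in the knockout library were of mixed function. WT nuclei of this class came mostly from clusters 0, 1 and 6 and knockout nuclei mostly from clusters 5, 10, 11 and 16. Iigp1, an interferon-inducible GTPase, had the largest ratio, with 6 WT and 576 knockout UMIs (0.772 and 46.5 CPM; log2 ratio 5.80, 4.78 to 7.37). Igf1, the insulin-like growth factor, was at 7.85 and 92.3 CPM (log2 ratio 3.55, 3.18 to 3.95), and Irs1, the adaptor that couples the insulin and Igf1 receptors to PI3-kinase, at 204 and 1144 CPM (2.49, 2.42 to 2.57). The orphan nuclear receptors Nr4a3 and Nr4a2, which respond to muscle activity, had log2 ratios of 4.32 (3.89 to 4.80) and 3.10 (2.39 to 4.01). Sgms2, a sphingomyelin synthase, was at 4.76 and 138 CPM (4.84, 4.39 to 5.37).

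The other 6 of the 12 genes ranked highest were Lrrc3b (log2 ratio 3.78), the Z-disc protein gene Igfn1 (3.29), the protocadherin gene Pcdh7 (2.92), the phosphodiesterase gene Pde10a (2.86), Cpeb2, which encodes a regulator of translation (2.56), and the sorting receptor gene Sorcs1 (2.51). Between Y-marked nuclei all 12 had the whole interval above 2-fold. Inside the knockout library, however, 10 of the 12 were lower, with the interval below 0, in Xist-marked than in Y-marked myonuclei-like nuclei. Iigp1 was at 0.894 CPM in the former and 62.0 CPM in the latter, and Igf1 at 5.36 and 107 CPM, so that Xist-marked knockout nuclei set against Y-marked WT nuclei turned the Igf1 log2 ratio to −0.06. Sorcs1 was at 85.8 and 583 CPM, against 66.6 CPM in Y-marked WT nuclei. Iigp1 had 1 UMI in Xist-marked knockout nuclei and 1 in Y-marked WT nuclei, too few to compare. The rest of the 12 were higher in Xist-marked knockout than in Y-marked WT nuclei. Igfn1 was higher in Xist-marked nuclei, at 315 against 162 CPM. Nr4a3, Igfn1, Sorcs1, Sgms2 and Cpeb2 were also leading genes of clusters held mostly by the knockout library. Annotated genes overlap Pcdh7 and Cpeb2 on the same strand and Igf1, Irs1, Sgms2, Lrrc3b, Pde10a and Sorcs1 on the opposite strand, and whether counting used strand is not given in the sources used here, so part of their UMIs is of uncertain origin.

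Most of the 12 genes ranked lowest in knockout myonuclei-like nuclei were long, 8 of them above 300 kb. Unc5d, a netrin receptor gene, was at 23.9 CPM in WT and 0.727 CPM in the knockout (log2 ratio −4.97, −6.19 to −4.08), and Gria1, an AMPA receptor subunit gene, at 12.6 and 0.485 CPM (−4.59, −6.18 to −3.53). The neural adhesion genes Chl1 (−4.44) and Cntn4 (−4.28), the reelin adaptor gene Dab1 (−4.25), the prohormone convertase gene Pcsk2 (−4.91), the potassium channel partner gene Dpp10 (−4.04), Lrp1b (−4.20) and Egfem1 (−4.35) went the same way. Dytn, a relative of dystrophin, had the lowest ratio, with 144 WT and 4 knockout UMIs (−5.68, −7.74 to −4.45), and Arrdc2, an arrestin-domain gene and like Dytn a leading gene of the WT-dominated cluster 1, was at 199 and 14.0 CPM.

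Between Y-marked nuclei, 11 of these 12 genes had the whole interval beyond 2-fold, and that of Dytn, from 5 and 2 UMIs, reached past 0 (log2 ratio −2.40, −5.97 to 0.03). The same 12 genes were also lower in the other classes: of the 11 with at least 5 UMIs in each class, all were lower in fibro-adipogenic-like, in macrophage-like and in adipocyte-like nuclei, with the interval below 0 for 10, 9 and 10 of them. These classes also carried muscle RNA. Their Ttn was at 65.4%, 55.6% and 32.1% of the myonuclei-like level in WT, and at 34.9%, 50.2% and 16.6% in the knockout. Part of these differences may therefore be carried over from muscle. Their median length was 485 kb in the GRCm38 annotation, against a median of 68.5 kb for the 12 genes ranked highest. Over all genes at 1 to 100 CPM, the median log2 ratio went from 0.05 (0.01 to 0.09) in the shortest of 5 equal groups by length to −1.85 (−1.999 to −1.74) in the longest. Unc5d, Lrp1b (chromosome 2, 40595246 to 42653624), Chl1, Dab1, Dpp10 and Egfem1 overlap other annotated genes on their own strand and Dytn and Pcsk2 on the opposite strand, which leaves part of their UMIs uncertain. Chl1 was also a leading gene of the unnamed cluster.

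**Figure D2:**
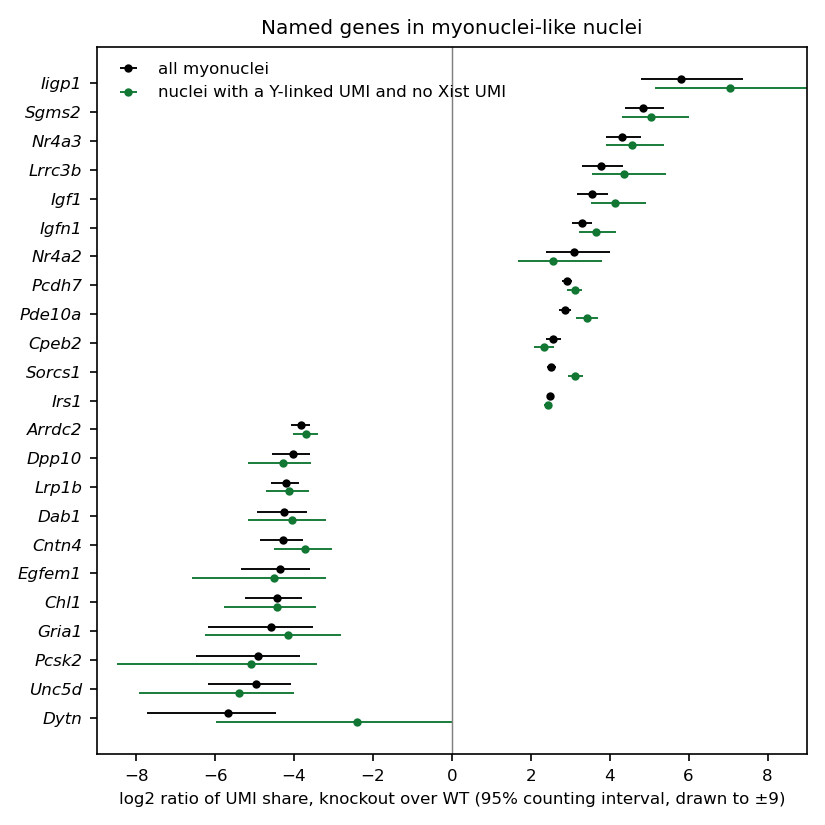
Log2 ratio of UMI share, knockout over WT (x axis), for the genes named by rank in myonuclei-like nuclei (y axis), over all such nuclei (black) and over those with a Y-linked UMI and no Xist UMI (green). Lines are exact 95% counting intervals drawn to ±9; the 12 higher genes stay above 0 in both sets, and the interval of Dytn reaches 0.03 in the second.

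**Figure D3:**
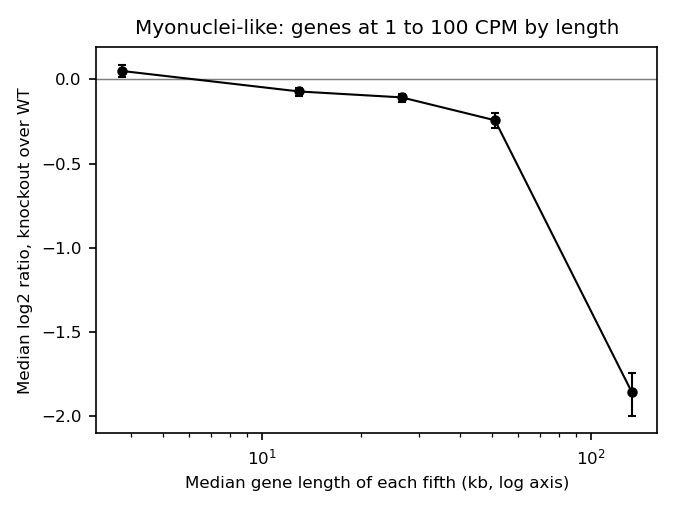
Median log2 ratio, knockout over WT (y axis), against median gene length in kb on a log axis (x axis), for 5 equal groups by length of the genes at 1 to 100 CPM in myonuclei-like nuclei. Error bars are order-statistic 95% intervals of the median; the group of the longest genes (2762) lies at −1.85 and that of the shortest (2763) at 0.05.

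Gene lists fixed in advance showed lower transcripts for the use of fatty acids in knockout myonuclei-like nuclei. Of 20 measured members of the fatty acid use and PPAR list, 18 were lower, 15 of them with an interval below 0, and 2 were higher. The median log2 ratio was −0.66 (−0.95 to −0.30), below every one of 10000 random lists matched on expression. The lipid droplet coat gene Plin5 (−1.98) and the fatty acid binding protein gene Fabp3 (−1.43) were lowest. Pdk4, which restrains glucose oxidation (−1.26), and the receptor gene Ppara (−1.18), named after their values were seen, were close behind. Plin2, the common lipid droplet coat gene, was higher (0.94), and Ppargc1a was near 0 (0.10). The median kept its direction under every alternative tried, but was −0.25 in nuclei thinned to 500 UMIs and −1.22 in nuclei with at least 500 genes.

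The list of immediate early genes, the first to be transcribed after a stimulus, and of heat shock genes had a median of 0.86 (−0.37 to 2.32) at percentile 100 of the random lists. This median was 1.63 in thinned nuclei and 0.43 for Xist-marked knockout nuclei set against Y-marked WT nuclei. Of 9 measured members, 5 had an interval above 0 and 2 below, with Egr1 at 3.57 (2.51 to 5.15) and Fosb at 2.32 (1.20 to 3.93), whereas Jun was at −1.06 and Atf3 at −0.37. The slow contractile list had a median of 0.61 (−0.56 to 1.23) at percentile 99.9, with Tnnc1 at 2.16 and Atp2a2 at 1.23 but Casq2 at −0.60 and Mybpc1 at −0.56; the median was −0.70 among Myh4-led nuclei, −0.65 in nuclei with at most 1% mitochondrially encoded UMIs and −0.34 between Y-marked nuclei, but 2.80 in Xist-marked knockout nuclei against Y-marked WT nuclei. The fast contractile list had a median of −0.16 at percentile 1.54, with 7 of 11 members having an interval below 0, among them Tnnt3 at −1.51, and with Myl1 at 0.64; it turned to 0.24 in nuclei with at least 500 genes and to 0.06 at resolution 0.5. The p53 and damage list had a median of 0.31 (−0.06 to 1.65) at percentile 95.4, with 3 of 8 members having an interval above 0, led by Phlda3 (1.65); the median was 0.13 among Myh4-led nuclei and 0.01 for Xist-marked knockout nuclei set against Y-marked WT nuclei.

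Insulin and glucose uptake genes split, with a median of −0.07 (percentile 4.07): Irs1 and Irs2 (1.43) were higher, and Pik3r1 (−0.96) and Grb10 (−1.21) lower. The remaining coat genes of caveolae did not share the loss of Cavin1: their median was −0.39 (−1.81 to 0.34), with the muscle caveolin gene Cav3 at 0.34 (0.02 to 0.67), Cavin4 at 0.09 (−0.14 to 0.33) and Cavin2, with 16 and 7 UMIs, at −1.81 (−3.39 to −0.50). In the dystrophin complex (median 0.22) the laminin gene Lama2 was at 2.31 and Sgcd at 1.08, while the syntrophin gene Sntb1 was at −2.77. Membrane repair genes had a median of 0.14, with Anxa5 at 1.65 and Myof at −2.73, and denervation response genes a median of 0.20, with Runx1 at 2.12 and Chrna9 at −3.48; the latter median was −0.32 among Myh4-led nuclei, −0.13 at resolution 0.5 and 0.84 between Y-marked nuclei. Atrophy genes had a median of −0.06, with Eda2r at 2.00 and Foxo1 at −1.42. RNA polymerase I genes had a median of −0.23 (percentile 7.26). Ribosomal protein genes had a median of −0.40 (60 of 74 lower, 19 with an interval below 0), at percentile 29.96 of lists matched on expression. Those lists were not matched on length. The ribosomal protein genes taken by the list rule are 2.2 to 3.6 kb long, and the shortest group of genes by length, up to 7.9 kb, had a median of 0.05.

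The other lists had medians near 0 in myonuclei-like nuclei: 0.13 for embryonic and regeneration genes (3 measured), 0.09 for glycolysis and glycogen, −0.04 for nuclear-encoded oxidative phosphorylation, 0.09 for excitation-contraction coupling, where Hrc was at −2.42, 0.04 for the unfolded protein response, −0.10 for autophagy and lysosome, where Ctsd was at −1.77, 0.24 for interferon response (3 measured) and 0.03 for the circadian clock. The interferon median turned to −1.16 with the unnamed cluster counted as myonuclei. Mitochondrially encoded transcripts had a median of −0.43 (−1.39 to 0.14), which ranged from −0.73 to 0.73 over the alternatives. Other medians that took both signs over the alternatives ranged from −0.49 to 0.16 for caveola coat, −0.22 to 0.27 for insulin, −0.10 to 0.50 for membrane repair, −0.20 to 0.20 for atrophy, −0.53 to 0.23 for oxidative phosphorylation, −0.11 to 0.33 for unfolded protein, −0.27 to 0.28 for autophagy and −0.16 to 0.24 for clock genes, and by less for glycolysis and for excitation-contraction coupling. Too few cell cycle genes were measured for a median in any class.

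**Figure D4:**
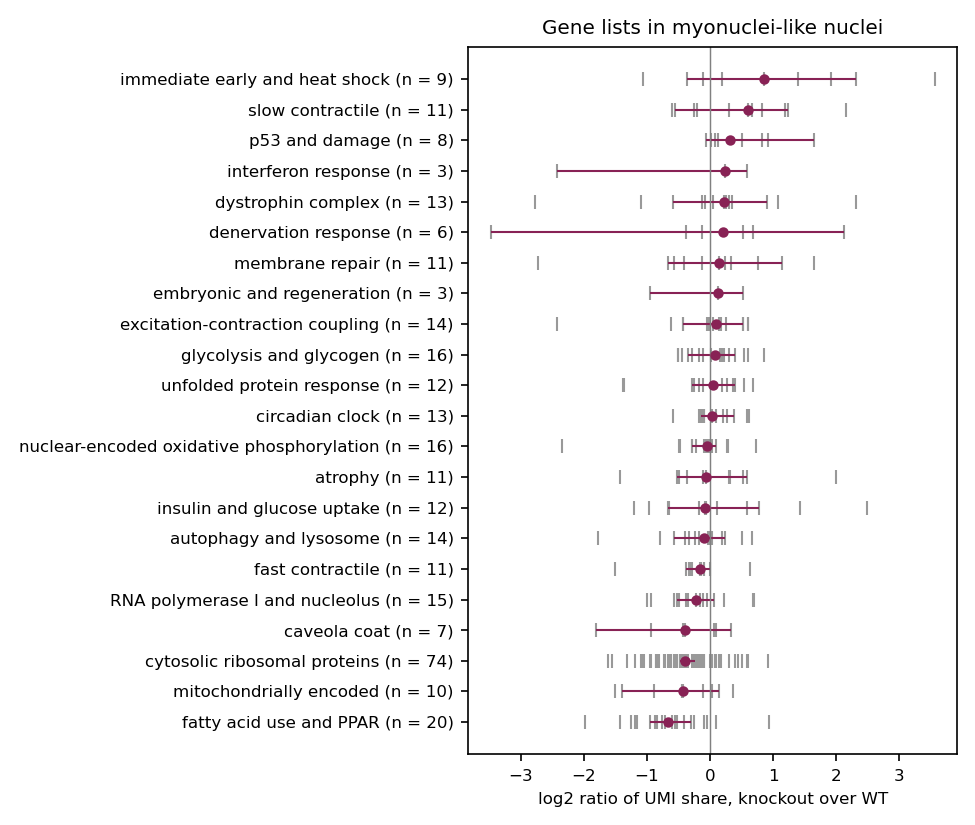
Log2 ratio of UMI share, knockout over WT (x axis), of the measured members (grey ticks) of each gene list (y axis, n measured in brackets) in myonuclei-like nuclei. Points are list medians and lines their order-statistic 95% intervals; the fatty acid use and PPAR list lies lowest, at −0.66, and the immediate early and heat shock list highest, at 0.86.

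In fibro-adipogenic-like nuclei, all from cluster 8 in both libraries, genes of the fibrillar matrix and adipogenic lists were higher in the knockout, the former on balance not once muscle RNA was subtracted. Among the genes ranked highest, Plod2, a lysyl hydroxylase of collagen cross-linking, was at 16.0 and 145 CPM (log2 ratio 3.07, 2.00 to 4.66), Svep1, an extracellular adhesion protein gene, at 90.8 and 446 CPM (2.28, 1.78 to 2.85), Ldb2, a transcriptional cofactor gene, at 102 and 485 CPM (2.24, 1.77 to 2.78) and also a leading gene of the blood endothelial-like cluster, and Pcdh7 at 371 and 1505 CPM (2.01, 1.76 to 2.28). Between Y-marked nuclei Svep1 was at 2.48 (1.45 to 3.94), Ldb2 at 1.41 (0.41 to 2.70), Pcdh7 at 1.47 (1.06 to 1.92) and Plod2 had 0 and 23 UMIs. Inside the knockout library Ldb2, at 806 against 208 CPM, and Plod2, at 276 against 114 CPM, were higher in Xist-marked than in Y-marked nuclei. In this class 22 knockout nuclei held both signals, against 107 with Xist alone. Some Y-marked nuclei may thus express Xist, and their share was not computed. All 14 measured fibrillar matrix genes were higher, 9 with an interval above 0, with a median of 0.92 (0.27 to 1.45; percentile 99.8), led by the proteoglycan genes Lum (2.68, 1.00 to 6.09, from 2 and 30 UMIs) and Dcn (1.77, 1.39 to 2.19). Of the 4 measured adipogenic genes (median 0.97), 3 had an interval above 0, Fabp4 at 2.15, Lpl at 1.07 and Ebf2 at 0.33, while that of Pparg included 0 (0.87, −0.12 to 2.10). Fabp4 and Pparg were also leading genes of the adipocyte-like cluster 18, held mostly by the knockout library, and RNA from adipocytes was not subtracted.

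The median gene with at least 100 UMIs in this class had a log2 ratio of 0.39, and that with at least 20 UMIs 0.29. Relative to the former, used for every value scaled to a median gene here, 10 of the 14 fibrillar matrix genes and 3 of the 4 adipogenic genes were higher, and the medians were 0.53 and 0.58; Ebf2 lay between the 2 median genes. The Ttn level of these nuclei was 65.4% of that of myonuclei-like nuclei in WT and 34.9% in the knockout. With a muscle profile subtracted in proportion to Ttn, the fibrillar matrix median was 0.05, with members from −0.75 (Fbn1) to 1.94 (Lum), the adipogenic median was 1.02 with Ebf2 at −0.57, and the 4 genes ranked highest lay between 1.10 and 2.24.

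Relative to the median gene, the other lists in fibro-adipogenic-like nuclei had medians of −0.03 for TGF-beta response (0.35 before this scaling), with Skil at 1.53 before it, −0.06 for cytokine and complement (0.33 before it), 0.06 for caveola coat, where Cav1 was at 1.93 (0.94 to 3.28) before it, 0.36 for immediate early, −0.58 for circadian clock and −1.34 for mitochondrially encoded genes, of which 6 of 6 were lower, 3 with an interval below 0 before it. The clock median, −0.20 before this scaling, was 0.75 in nuclei thinned to 500 UMIs and −0.01 with the muscle profile subtracted, and the caveola coat median, 0.44 before it, was −0.06 for Xist-marked knockout nuclei set against Y-marked WT nuclei. Over the alternatives the cytokine and complement median ranged from −0.565 to 0.978 and that of TGF-beta response from −0.134 to 0.57. Lowest were the neural adhesion genes Cntnap5b (34 and 1 UMIs; −5.45, −11.4 to −3.44), Cadm2 (−4.60, −6.68 to −3.32) and Cdh18 (46 and 3 UMIs; −4.66, −7.19 to −3.23), and the ligand gene Wnt2 (34 and 2 UMIs; −4.71, −8.12 to −3.05). The first 3 are long, at 713.2, 965.5 and 925.4 kb, like most of the lowest genes of myonuclei-like nuclei, and Cadm2 was a leading gene of the unnamed cluster.

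Macrophage-like nuclei, all from cluster 3, had higher Apoe in the knockout over all nuclei of the class, though not clearly between Y-marked ones. Apoe, the lipid-carrying apolipoprotein of lipid-handling macrophages, had 4 and 98 UMIs (31.1 and 332 CPM; log2 ratio 3.25, 2.01 to 5.32). Between Y-marked nuclei it had 1 and 16 UMIs, with an interval that includes 0 (1.81, −0.33 to 7.74), and inside the knockout library it was higher in Xist-marked than in Y-marked nuclei (1.53, 0.61 to 2.53). Ltbp1, which encodes a binder of latent TGF-beta (3.08, 2.30 to 4.11), and Dennd4a (3.24, 2.19 to 4.82) were also higher. Of the 5 measured resident macrophage genes, 3 had an interval below 0 and none above, with a median of −0.30 (−1.55 to −0.06), or −0.56 relative to the median gene of the class, and with the haemoglobin scavenger receptor gene Cd163 at −1.55 (−2.27 to −0.85), but the median was 0.50 in nuclei thinned to 500 UMIs and −1.39 in nuclei with at least 500 genes. The lipid-associated list, which also holds Apoe, had no common direction, with Lgals3 at 1.19, Lpl at −0.85 and a median of 0.17, or −0.10 relative to the median gene. On that scale circadian clock genes had a median of −0.49 and mitochondrially encoded genes −0.12 (0.14 before it). Over the alternatives the lipid-associated median ranged from −0.66 to 0.34 and the mitochondrially encoded one from −0.709 to 0.136. Lowest were Lrp1b (−4.44), Cntnap2 (−3.52), Kcnab1 (−3.18) and Lsamp (−3.02), all of at least 268.8 kb; Kcnab1 was a leading gene of the WT-dominated cluster 6. The median gene with at least 100 UMIs had a log2 ratio of 0.26, and that with at least 20 UMIs 0.22. The Ttn level of the class was 55.6% of that of myonuclei-like nuclei in WT and 50.2% in the knockout.

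Of the 4 genes ranked highest in knockout adipocyte-like nuclei, 3 encode enzymes that make or extend fatty acids. Elovl6, the fatty acid elongase, had 2 and 1719 UMIs (7.96 and 861 CPM; log2 ratio 6.44, 4.90 to 9.80), Acaca, acetyl-CoA carboxylase, was at 426 and 4861 CPM (3.51, 3.24 to 3.80), and Acly, ATP citrate lyase, had 1 and 385 UMIs (5.02, 3.11 to 10.9). The galactosyltransferase gene B3galt1 was at 103 and 1266 CPM (3.59, 3.06 to 4.23). Different clusters held most of the class, cluster 7 with 243 of 253 WT nuclei and cluster 18 with 975 of 1062 knockout nuclei, and Elovl6 was a leading gene of cluster 18. Between Y-marked nuclei of the class, Acaca was at 341 and 4327 CPM (3.65, 3.19 to 4.18); of the 794 knockout nuclei of the class with Xist, 94 also held Y-linked UMIs.

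The caveolin genes were higher in these nuclei, with Cav1 at 466 and 790 CPM (0.76, 0.49 to 1.05) and Cav2 at 1.83 (0.23 to 5.21, from 2 and 70 UMIs), while Cavin4, from 6 and 22 UMIs, was at −1.20 (−2.46 to 0.48). The median gene with at least 100 UMIs had a log2 ratio of 0.35, and that with at least 20 UMIs 0.15. Relative to the former, the list medians were −0.50 for caveola coat genes (−1.17 between Y-marked nuclei and 0.30 in thinned nuclei before this scaling), 0.55 for immediate early genes, −0.72 for interferon response genes (3 measured), −0.14 for the circadian clock, which was 0.21 before it, with Arntl at −1.84, and 0.15 for mitochondrially encoded genes. Lowest were Mageb18 (47 and 6 UMIs; −5.86, −7.48 to −4.73), the homeobox gene Cux2 (−5.70), the calcium channel gene Cacna1e (−4.25), also a leading gene of the lymphocyte-like cluster, and Lrp1b (−4.38). Ttn was at 32.1% of the level of myonuclei-like nuclei in WT and 16.6% in the knockout. Lists for endothelial and satellite cells were not analysed here, because 1 library or both held fewer than 100 such nuclei.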

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

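The 3 tests on adipocyte-like nuclei and the tests of dilution as the whole cause, of free ribosomal RNA and of RNA polymerase I genes were chosen only after the result was seen, whereas the depth test on Rn18s and both tests on long genes were chosen before.

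Xist stood out because the knockout library held 4358 UMIs of it and the WT library 4, and it marked most adipocyte-like nuclei of the knockout, whose share was 13.7% against 2.46% in WT. Sequencing depth is argued against, since the difference among nuclei with at least 1000 UMIs was still 9.16 percentage points. Among Y-marked nuclei the knockout to WT ratio of the adipocyte-like share was 0.812 (0.585 to 1.13). Xist-expressing nuclei with stray Y-linked UMIs could make up 42.3% (up to 51.1%) of the 75 knockout nuclei behind this ratio, so its size is uncertain. As the share was not higher there, a candidate explanation is adipose tissue carried over with donors of 1 sex. Loss of Cavin1 acting in Xist-expressing animals cannot be told apart from this, because only 2 WT nuclei carried Xist alone. Genotype and the amount of fat left on the dissected muscle stay open and untested.

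Rn18s made up 8.07% of WT and 2.90% of knockout UMIs. At matched depth, in myonuclei-like nuclei of 1000 to 2000 UMIs, the knockout to WT ratio of its share was 0.515 (0.511 to 0.519), and it was 0.498 and 0.620 in the shallower and deeper bins. All 3 lie far below the 0.8 set for dilution by deeper nuclei as the whole cause, which argues against it. Over all myonuclei-like nuclei the ratio was 0.384, below that of each bin. From the shallowest to the deepest bin the share fell from 9.57% to 4.30% in WT and from 4.77% to 2.67% in the knockout. Part of the difference over all these nuclei therefore goes with depth. The depth test itself was undecided, since its value of 0.515 was not below the bound of 0.5 set for no dilution. The knockout to WT ratios of the 4 classes, from 0.322 to 0.384, lay within 1.195-fold of each other, as free ribosomal RNA shared by all droplets of the WT suspension would give, and this explanation may hold. The RNA polymerase I list had a median of −0.226 in myonuclei-like nuclei with an interval of −0.524 to 0.058, which decides neither way. Genotype stays open as untested.

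The unnamed cluster led by repeat-rich and long neuronal transcripts stood out with 1425 WT nuclei against 20 in the knockout, and 8 of the 12 genes ranked lowest in knockout myonuclei-like nuclei were also above 300 kb. The other 4 were Pcsk2 (270.1 kb), Chl1 (239.6 kb), Dytn (64.1 kb) and Arrdc2 (4.6 kb). Summed over 1471 olfactory and vomeronasal receptor genes, which muscle should hardly transcribe, the WT to knockout ratio was 4.68 (4.45 to 4.93), from 568 and 121 CPM. Over 5 equal groups of genes by length, the median log2 ratio of the longest group less that of the shortest was −1.905. Both values are consistent with reads spread over the genome without transcription in the WT library, such as from genomic DNA, which would fall on genes in proportion to length. Genotype stays open as untested, and no test here separates a true loss of transcripts from long genes from such reads.

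Several genes went one way in one class and the other way in another, and none of these differences was tested. Svep1 was higher in fibro-adipogenic-like (log2 ratio 2.28) and adipocyte-like nuclei (1.91) and lower in myonuclei-like nuclei (−1.82). Ldb2 was higher in fibro-adipogenic-like (2.24) and lower in myonuclei-like nuclei (−1.88). Lsamp was higher in fibro-adipogenic-like nuclei (1.43) and lower in myonuclei-like (−3.40) and macrophage-like nuclei (−3.02). Sntb1, a syntrophin gene, was higher in adipocyte-like nuclei (1.32) and lower in myonuclei-like nuclei (−2.77). All of these genes are long: Svep1 spans 164.4 kb, Ldb2 327.5 kb, Lsamp 2197.3 kb and Sntb1 270.6 kb. In myonuclei-like nuclei the longest group of genes by length, from 76.2 kb, had a median log2 ratio of −1.85. Their lower values in that class cannot be told apart from this shift of long genes.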

How the results depend on the processing

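Alternatives chosen only after the data were seen were the removal of high doublet scores, the repeat-led cluster counted as myonuclei, the split by Xist and Y-linked UMIs, and the subtraction of muscle RNA. Of 1221 alternative values, 1017 kept the direction and lay within the counting interval of the reported value, 193 lay outside that interval, some uncalled ones with the other sign, and 11 called values turned direction; for the 48 genes named by rank these counts were 526, 97 and 1 of 624, the 1 being Igf1. No paired analysis was possible because each genotype has 1 library. Keeping doublets gave the same values as the reported ones, since none had been marked, and is void. Endothelial, satellite and several list values were not obtained where fewer than 100 nuclei or 3 members were left. Depth limits genes of few UMIs most, and 2055 WT nuclei drop out when thinned. Except where construction shows it, the cause was not tested.

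Shares below are knockout minus WT in percentage points, and list values are median log2 ratios. With at least 500 genes per nucleus, the differences were 29.6 for myonuclei-like, 1.31 for fibro-adipogenic-like, 9.29 for adipocyte-like and 1.61 for macrophage-like nuclei, and 36.3, −20.4, −16.4 and 0.461 for Myh4, Myh1, Myh2 and Myh7. The lists were at 0.242 for fast contractile, −1.22 for fatty acid use and −0.528 for oxidative phosphorylation genes. With at most 1% mitochondrially encoded UMIs, they were −1.68 for myonuclei-like and 1.96 for macrophage-like nuclei, 13.05 for Myh4, −6.79 for Myh1 and −0.028 for Myh7, with slow contractile genes at −0.649 and the macrophage clock list at 0.101.

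At resolution 0.5, where 5547 WT nuclei fell into unnamed repeat-led clusters, they were 32.6 for myonuclei-like and 2.07 for macrophage-like nuclei, and 27.1, −15.5 and −12.0 for Myh4, Myh1 and Myh2, with fast contractile genes at 0.064, fatty acid use at −0.974 and oxidative phosphorylation at −0.326. With each library clustered on its own, they were 5.40 for myonuclei-like and −2.04 for fibro-adipogenic-like nuclei, and 13.6, −7.56 and −6.63 for Myh4, Myh1 and Myh2, with fibrillar matrix genes at 1.80. With at least 1000 UMIs, they were 0.377 for fibro-adipogenic-like, 9.16 for adipocyte-like and 0.419 for macrophage-like nuclei.

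In nuclei thinned to 500 UMIs, the Myh4, Myh1 and Myh2 differences were 8.82, −5.00 and −4.34, with ribosomal protein genes at −0.508, fatty acid use at −0.253, oxidative phosphorylation at 0.229 and resident macrophage genes at 0.50. Among Myh4-led myonuclei, the lists were at −0.705 for slow contractile, 0.100 for oxidative phosphorylation and −0.152 for clock genes; the first leaves out slow nuclei by construction. Median-of-ratios scaling put clock genes at −0.139 in adipocyte-like and −0.490 in macrophage-like nuclei and adipocyte interferon genes at −0.720. Totals without the most abundant genes put ribosomal protein genes at −0.493 and adipocyte interferon genes at −0.515.

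Removing the top 6% of doublet scores gave −0.924 for myonuclei-like, 2.24 for fibro-adipogenic-like, 10.2 for adipocyte-like and 2.04 for macrophage-like nuclei, 12.7 for Myh4 and −7.12 for Myh1. Counting the repeat-led cluster as myonuclei gave −19.4 for the class and 9.36, −4.89 and −5.06 for Myh4, Myh1 and Myh2. Subtracting muscle RNA put fibro-adipogenic fibrillar matrix genes at 0.046, TGF-beta response at −0.134 and immediate early genes at 0.081, and adipocyte interferon genes at −0.657.

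Between Y-marked nuclei, the differences were 7.38 for myonuclei-like, 0.606 for fibro-adipogenic-like, −0.560 for adipocyte-like and 0.279 for macrophage-like nuclei, and 18.1, −9.44, −8.76 and 0.074 for Myh4, Myh1, Myh2 and Myh7, with oxidative phosphorylation at −0.414 and the macrophage clock list at −0.525. Xist-marked knockout against Y-marked WT nuclei gave −43.7 for myonuclei-like, 42.9 for adipocyte-like and 1.68 for macrophage-like nuclei, and −2.88, −0.111, −1.39 and 4.38 for Myh4, Myh1, Myh2 and Myh7. In that comparison the lists were at 2.80 for slow contractile, −0.244 for fatty acid use, 0.284 for autophagy, −0.158 for clock and 0.725 for mitochondrially encoded genes. Igf1 was at −0.063, and Cavin1, with 0 knockout UMIs and 0.5 added, at −2.87 in myonuclei-like nuclei, which is no bound.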

Other observations

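The test on nuclei with at least 3 Y-linked UMIs was chosen after the result was seen and the other 2 tests before; the genes in the first paragraph were chosen after their values were seen.

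Some adipocyte genes differed over all nuclei. Ucp1, the uncoupling protein of thermogenic adipocytes, had 2 UMIs in all WT nuclei and 147 in all knockout nuclei (log2 ratio 5.16, 3.60 to 8.54), and Cidea, a lipid droplet protein gene of the same cells, had 26 and 322 (2.89, 2.33 to 3.55). Adipoq, the adiponectin gene of all adipocytes, had 36 and 390 UMIs (2.70, 2.22 to 3.25), whereas Lep, the leptin gene, had 24 and 47 (0.24, −0.49 to 1.02), and Ppargc1a, a regulator of thermogenic genes that muscle also expresses, was at 0.125 (0.054 to 0.196). In adipocyte-like nuclei the fatty acid synthase gene Fasn had 7 and 818 UMIs (3.78, 2.83 to 5.20) and the desaturase gene Scd1 36 and 1275 (2.14, 1.68 to 2.68). The lipogenic regulators Srebf1 and Mlxipl were closer between the libraries, at 1.02 (0.27 to 2.00) and 0.49 (0.18 to 0.83).

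Marker UMIs of further cell types, some without a cluster of their own, were also summed over all nuclei, and only some differed. Schwann cell markers had a knockout to WT ratio of 1.35 (1.20 to 1.51) and perineurial markers, from 57 and 33 UMIs, 0.354 (0.222 to 0.549). Tenocyte markers were at 0.725 (0.590 to 0.892), dendritic cell or monocyte markers at 0.865 (0.678 to 1.11), mast cell markers at 0.966 (0.718 to 1.31), neutrophil markers at 0.576 (0.354 to 0.932) and erythroid markers at 0.910 (0.752 to 1.11). Pericyte markers were at 1.24 (1.19 to 1.30), against 0.289 for smooth muscle. Markers of immature myonuclei were at 1.07 (0.949 to 1.21), those of the neuromuscular junction at 1.23 (1.17 to 1.29) and those of the myotendinous junction at 0.714 (0.667 to 0.764).

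The fatty acid synthesis genes of adipocyte-like nuclei could reflect the sex or donor of the nuclei, since 90.3% of knockout nuclei of this class with 1 of the 2 signals carried Xist. Between Y-marked nuclei, 81 in WT and 75 in the knockout, the median log2 ratio of Elovl6, Acaca and Acly was 5.368, against 5.02 over all nuclei. Of the 794 knockout nuclei of the class with Xist, however, 94 also held Y-linked UMIs, so that Xist-expressing nuclei could supply up to 63.3% of the UMIs of the 75, and sex or donor cannot be told apart from genotype by this value. In the Y-marked nuclei Elovl6 had 0 and 212 UMIs and Acly 0 and 40. With WT set to a floor of 3 UMIs, they were 36.0-fold and 6.80-fold higher. Their exact log2 intervals ran from 4.86 and 2.40 upwards, and with both at that floor the median was 3.67. In the 20 knockout nuclei with at least 3 Y-linked UMIs and no Xist, the same bound is 51.6%. There the 3 genes were at 0.971 (0.780 to 1.186), 0.827 (0.750 to 0.909) and 1.082 (0.652 to 1.639) times their level in Xist-marked nuclei. By counting error alone, this argues against Xist-expressing nuclei as the only source of these 3. Nuclei were placed in the class by expression, however, and Elovl6 was a leading gene of cluster 18, so similar levels go in part with membership. Spread between the 20 nuclei is not covered either, so the test does not settle the question. In the 75 Y-marked knockout nuclei, Fasn was at 235 CPM against 486 CPM in Xist-marked ones, and B3galt1 at 713 against 1433 CPM. Xist-expressing nuclei alone could give both of these levels. Scd1 (535 and 678 CPM), Srebf1 (103 and 111 CPM) and Mlxipl (615 and 493 CPM) lay closer. Genotype, the depot the adipocytes came from and other differences between donors stay open and untested.

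Large differences in myonuclei-like nuclei might stem from passenger DNA of another strain kept around the targeted gene. Within 10 Mb of Cavin1, 6 of 145 genes lay beyond 2-fold, against 31 of 541 on the rest of chromosome 11, a ratio of shares of 0.722 (0.246 to 1.76) whose interval stays below the 2-fold excess set as the mark of such DNA, and 669 of 8220 on the other chromosomes. This argues against an excess of large differences within 10 Mb of the gene, while leaving single genes near the locus open. With only 145 genes, the window could not have been a main source of such differences in any case. Passenger DNA over a longer stretch of chromosome 11 was not tested, since the rest of that chromosome served as the comparison.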
